A study of Homo sapiens with 12 samples.

How the data were processed

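RNA sequencing libraries of human keloid material were analysed from gene tables that the authors deposited, with 4 groups of 3 libraries. Primary keloid fibroblasts, cultured cells grown out of the raised scars called keloids, received a control siRNA (siControl) or an siRNA against RUNX2 (siRUNX2) by nucleofection, and RNA was taken 72 h later, per the labels' protocols. The other groups were keloid tissue and normal skin. Per the labels' protocols, RNA came from a lipid tissue kit and libraries from a stranded mRNA kit. The tissue libraries hold 22.9% to 55.5% mitochondrial ribosomal RNA and up to 1.76% RN7SK, which is unusual for an mRNA kit, and the files do not settle whether the named kit was used for them. Per the submitters' processing notes, FastQC 0.11.2, TopHat, Picard, featureCounts and edgeR were used with the hg19 build.

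The fibroblast table holds TPM values that the authors computed per gene and library, and each column sums to 1000000 in the deposited values. TPM keeps no depth, so the number of reads behind a fibroblast value is unknown. The lowest values give the relative worth of 1 read, which lay between 0.841 and 1.03 of that in siControl 1. The tissue table holds scaled CPM, a signal that the authors obtained from gene counts by a scaling to the library size and a further factor per library. Each tissue value was a whole multiple of a fixed step per library within a tolerance of 0.01, and 100% of values came out whole. The recovered totals were 1.25e+07 to 1.97e+07 reads per library. The scaling factors in the deposited CPM matched trimmed-mean (TMM) factors computed from the recovered reads within 0.1%. Intervals and floors from such reads cover counting error alone, and 3 reads correspond to 0.146 to 0.304 CPM.

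There are 27778 genes in the TPM values and 39393 in the CPM values. XIST, TSIX and genes of the Y chromosome (26 and 101 entries) were left out of all results. Gene type, transcript length and GC content came from GENCODE 29 through the Ensembl identifier, which 26291 and 36744 of them matched. That release belongs to another genome build than the files, so no coordinates are given. There were 0 unused columns of values per sample.

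Each comparison was fitted on its own 6 libraries, since the tables were normalized separately. Values were tested as log2(value + 1) with limma 3.58.1 (moderated, with a mean-variance trend), for genes with a mean of at least 1. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. This tested 15302 genes in fibroblasts and 16349 in tissue. All tests were two-sided. R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used, the last 2 on the recovered tissue reads as alternatives, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

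Lists of genes, 38 in all, for matrix, signalling, cell state, sample quality and skin cell types were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 3 tested members, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry asks whether its genes move one way on balance.

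The genes named in the text followed a rule fixed in advance. It takes RUNX2, the 8 largest rises and 8 largest falls among called protein-coding genes whose groups do not overlap, and up to 4 members per list with the smallest adjusted p. It adds the 6 genes with the largest sum of absolute log2 fold changes among those higher in keloid and lower after knockdown, where lower was read as an unadjusted p under 0.05 once no gene had passed, and allows every fibrillar collagen. Where fewer passed, those of smallest p were taken and are reported as not passing. Clone-style names, small RNA genes, pseudogenes, HLA genes and variable segments of immune receptors were not named.

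Sample numbers are shared between groups. Deviations from the group means correlated across genes at 0.23, 0.11 and 0.51 for the same-numbered fibroblast libraries, all above 0.1, so the numbers were taken to pair these libraries. The closest match of siControl 1 was still siRUNX2 2 (0.46), and that of siControl 2 was siRUNX2 1 (0.32). The check therefore leaves the pairing of samples 1 and 2 open. In tissue the correlations were -0.18, 0.39 and 0.51. The closest match of normal skin 1 was keloid 3 (0.21), and that of normal skin 2 was keloid 1 (0.41), so these correlations do not settle the tissue pairing. The library names of same-numbered normal skin and keloid samples carry a shared code, which the labels do not explain. On that basis differences within these pairs are given, and the fit with the replicate block serves as the paired alternative. The main fits have no block, so their p-values ignore any pairing. The fit with the replicate block is printed beside each call of a list that it changed and each count in the text that it moved by over 1.5 times. The labels do not say that replicates came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical.

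The procedures were tested on simulated data with the real means and spreads and 200 changed genes. The changed genes were drawn only from the more highly expressed tested genes, so recovery of low genes was not tried. For the fibroblast comparison, over 15302 genes, limma recovered 17.5% of genes changed 2-fold, 91.7% of those changed 4-fold and 96.7% of those changed 8-fold, with 8 false calls. For the tissue comparison, over 16349 genes, it recovered 2.5%, 71.7% and 93.3%, with 9 false calls. On simulated tissue reads edgeR recovered 1.25%, 36.7% and 93.3%, with 9 false calls. Camera recovered 5 of 5 shifted lists in each comparison with 0 false calls. The simulation has no differences between cultures or donors shared by many genes.

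Alternatives covered the pseudocount, the filter, the scaling, a robust prior, a fold minimum, the replicate block, leaving out each library, and count tests. Those added later are named in the closing section.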

Results

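RNA levels were measured in 12 libraries that form 4 groups of 3. Primary keloid fibroblasts carried a control siRNA or an siRNA against RUNX2, a transcription factor best known for bone and cartilage development, and keloid tissue was compared with normal skin. The fibroblast values are TPM of unknown depth. The tissue values are scaled CPM from 1.25e+07 to 1.97e+07 reads per library. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 took 55.5%, 37.4% and 46.4% of the reads in normal skin 1 to 3 and 22.9%, 36.7% and 48.9% in keloid 1 to 3. In fibroblasts they made up 1.26% to 1.95% of the TPM total. The non-coding RNA RN7SK took 0.177% to 1.76% of the reads in tissue.

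The first comparison asks what differs when RUNX2 is knocked down in keloid fibroblasts. RUNX2 (ENSG00000124813.16) was at 7.52, 9.19 and 18.1 TPM in siControl 1 to 3 and at 6.55, 4.08 and 10.6 TPM in siRUNX2 1 to 3. It was lower in each same-numbered pair, by a log2 difference of -0.18 in pair 1 and of -0.72 in pair 3, and by the most in pair 2. The group means were 11.6 ± 5.71 TPM and 7.08 ± 3.30 TPM (SD, n = 3 each). The log2 fold change of -0.63 (SE 0.41) did not pass the threshold, with a limma adjusted p of 0.498. For this gene alone the unadjusted limma p was 0.1715, or 0.0474 with the replicate block (adjusted p = 0.281). The pairing behind that block is open for samples 1 and 2.

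Fibrillar collagen genes, which encode the chains of the main collagen fibres, had lower values after knockdown. All 8 tested members were lower, with a median log2 fold change of -1.46 (2.76-fold lower). COL1A1 (ENSG00000108821.9) averaged 5926 ± 2522 TPM with siControl and 2001 ± 171 TPM with siRUNX2, a log2 fold change of -1.46 (SE 0.36, limma adjusted p = 0.278). Its partner chain COL1A2 averaged 5412 ± 1305 and 2278 ± 611 TPM. COL3A1 (ENSG00000168542.8) was at 879, 735 and 3006 TPM in siControl 1 to 3 and at 400.1, 161 and 1424 TPM in siRUNX2 1 to 3. COL5A1 averaged 421 ± 74.9 and 157 ± 90.1 TPM, and COL5A2 514 ± 165 and 253 ± 111 TPM. COL5A3 had a log2 fold change of -2.69. COL11A1 averaged 22.1 ± 26.2 TPM with siControl and 0.315 ± 0.163 TPM with siRUNX2. COL27A1 differed little, at 12.6 ± 13.7 and 8.41 ± 6.98 TPM. Over all genes 0 of the 8 passed limma, and 6 were lower when adjusted over the list alone (7 with the replicate block). As a list they were lower by camera (adjusted p = 4.32e-06), but not with an estimated correlation (adjusted p = 0.319).

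Of 36 matrix glycoprotein and proteoglycan genes 34 were lower, with a median of -1.51 (camera adjusted p = 5.71e-12, adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone 6 of them were lower, and 22 lower and 1 higher with the replicate block. Among them DPT, the dermatopontin gene, averaged 64.2 ± 48.9 and 1.45 ± 1.52 TPM, and THBS1, the thrombospondin-1 gene, 1460.1 ± 989 and 177 ± 18.0 TPM. FBN1, which encodes the microfibril protein fibrillin-1, averaged 762 ± 203 and 327 ± 49.4 TPM. Non-fibrillar collagens had a median of -0.44, with 17 of 18 lower (camera adjusted p = 0.000294, adjusted p = 0.356 with an estimated correlation). COL12A1 averaged 178 ± 95.5 and 70.1 ± 17.3 TPM. Genes for collagen processing had a median of -0.21, with 24 of 31 lower (camera adjusted p = 0.00017, adjusted p = 0.319 with an estimated correlation), among them the crosslinking enzyme gene LOXL2 at 647 ± 316 and 199 ± 25.1 TPM. Adjusted over the list alone 0 of the non-fibrillar collagens and 3 of the processing genes were lower by limma (4 and 5 with the replicate block). The matrix proteases went both ways, with 13 of 24 lower and a median of -0.23, and were not called (camera adjusted p = 0.0981), although MMP2, a gelatinase gene, averaged 1802 ± 1049 and 301 ± 154 TPM. Of the 24 proteases 0 were called adjusted over the list alone, and with the replicate block 2 were higher and 4 lower.

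All 16 tested myofibroblast contractile genes were lower after knockdown, with a median of -1.64 (3.12-fold lower, camera adjusted p = 1.74e-11, adjusted p = 0.319 with an estimated correlation). Of the 16, 13 were lower adjusted over the list alone. The myosin kinase gene MYLK averaged 32.0 ± 9.63 and 6.84 ± 3.99 TPM, and the collagen receptor gene ITGA11 164 ± 169 and 1.88 ± 3.14 TPM. The list of mesenchymal-type keloid fibroblast genes, which includes RUNX2 itself, had a median of -1.46 with 25 of 28 lower (camera adjusted p = 3.35e-08). Reticular fibroblast genes had a median of -1.48 (12 of 13 lower, adjusted p = 0.000229) and papillary fibroblast genes -0.76 (9 of 10 lower, adjusted p = 0.0293). Genes of TGF-beta signalling had a median of -0.60 with 21 of 27 lower (adjusted p = 0.00017). Among them was LTBP2, also in the matrix glycoprotein list, at 454 ± 261 and 110.5 ± 20.3 TPM. Pericyte and smooth muscle genes had a median of -0.58 (9 of 12 lower, adjusted p = 0.0485) and chondrocyte genes -0.65 (6 of 6 lower, adjusted p = 0.0184). The pericyte list shares genes with the contractile list, and the chondrocyte list with the collagen and matrix glycoprotein lists. The mesenchymal-type list shares genes with the collagen, processing, glycoprotein, protease, contractile and TGF-beta lists. The adjusted p with an estimated correlation was 0.502 for the papillary list and 0.319 for the other lists of this paragraph. Adjusted over the list alone, limma called 0 of the mesenchymal-type, 0 of the TGF-beta and 0 of the chondrocyte genes. With the replicate block 16 mesenchymal-type genes were lower and 1 higher, and 2 TGF-beta and 2 chondrocyte genes were lower. The papillary call ended with a correction for transcript length and GC content (median -0.72, adjusted p = 0.115). It also ended without siControl 3 (median -0.21, adjusted p = 0.321), siRUNX2 1 (-0.60, 0.119) or siRUNX2 2 (-0.25, 0.198). The pericyte call ended with that correction (median -0.40, adjusted p = 0.206) and without siControl 1 (0.189), siRUNX2 1 (0.0952) or siRUNX2 3 (0.0665). The chondrocyte call ended without siRUNX2 1 (median -0.32, adjusted p = 0.0952) or siRUNX2 2 (-0.32, 0.0633), and with no filter the chondrocyte median was -0.07.

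Interferon response genes were lower in 22 of 25 cases, with a median of -0.74 (camera adjusted p = 1.43e-05). Of the p53 response genes 18 of 20 were lower (median -0.43, adjusted p = 0.000157, with 1 lower adjusted over the list alone and 0 with the replicate block), among them CDKN1A at 757 ± 78.8 and 389 ± 204 TPM. Proliferation genes were higher in 39 of 40 cases, with a median of 0.83 (adjusted p = 3.35e-08), but the median was -0.16 between samples numbered 1. The replication licensing gene CDC6 averaged 16.5 ± 11.7 and 38.7 ± 13.7 TPM. Cytosolic ribosomal protein genes were higher by a median of 0.21 (48 of 50, adjusted p = 0.0049). That call ended with length and GC correction (median 0.10, adjusted p = 0.115) and without siControl 1 (0.565) or siRUNX2 3 (0.824). The adjusted p with an estimated correlation was 0.319 for interferon, 0.332 for p53, 0.502 for proliferation and 0.779 for ribosomal protein genes. In all, camera with its preset correlation called 13 of the 31 lists tested lower and 2 higher, and with an estimated correlation 0 were called (smallest adjusted p = 0.319), as by fry (smallest adjusted p = 0.107).

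The genes with the smallest p in limma did not pass the threshold either. Lower after knockdown were C9, a complement component gene (13.8 ± 1.63 and 3.60 ± 0.272 TPM), HMCN1, ARHGAP31, TRIM2, ZNF532, DDC8, HSPG2, which encodes perlecan (137 ± 10.9 and 42.9 ± 15.9 TPM), and LRP1. Higher were MT2A, a metallothionein gene (915 ± 401 and 3664 ± 808 TPM), PRSS3, CAMK2N1, UCHL3, EEF1E1, CCDC58, MRPS23 and NDUFV2. Each of these 16 had an adjusted p of 0.278.

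In all, limma called 0 of 15302 genes (smallest adjusted p = 0.278), and 0 with the replicate block. At an unadjusted p under 0.05 there were 2292 genes, 15.0% of those tested, where 765 would be expected by chance. The groups did not overlap for 3175 genes (20.8%, where chance gives 10%). Sample 3 stood apart. The log2 values of siControl 1 and 2 correlated at 0.968 and those of siRUNX2 1 and 2 at 0.973, whereas siControl 3 matched siRUNX2 3 (0.966) more closely than siControl 1 (0.891). Without siControl 3, limma called 90 genes higher and 141 lower, without siRUNX2 3 it called 4 higher and 0 lower, and without sample 3 in both groups, a fit added after the data were seen, 313 higher and 362 lower.

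**Figure D1:**
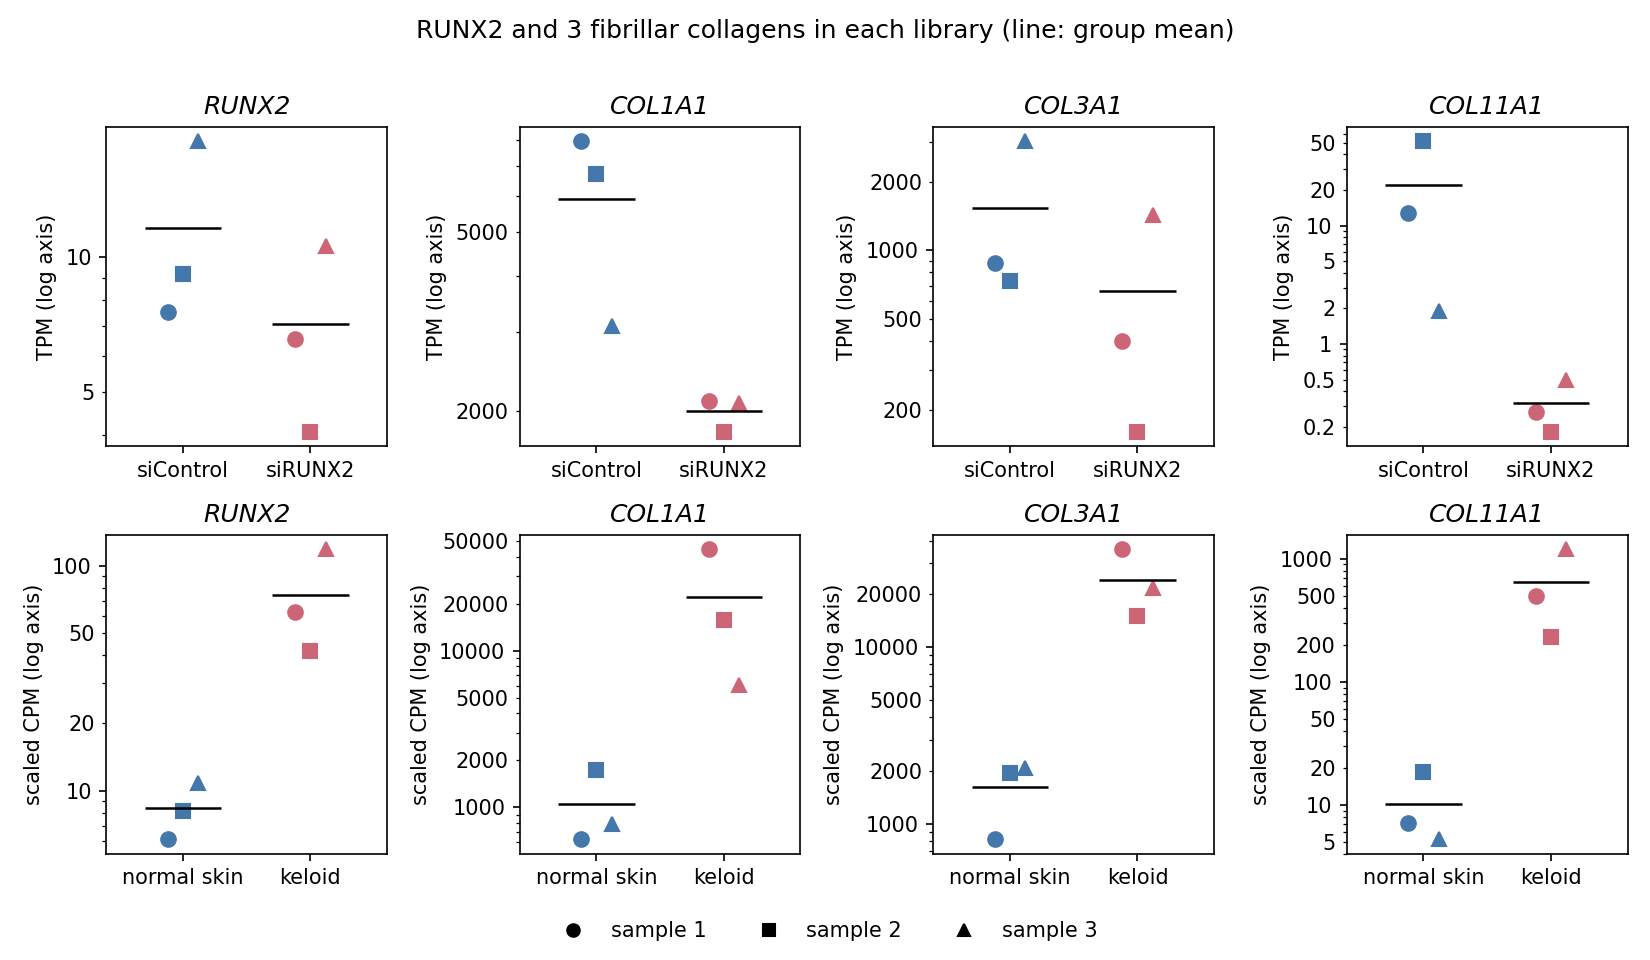
RUNX2, COL1A1, COL3A1 and COL11A1 in each library, on log axes, in TPM for fibroblasts (top) and scaled CPM for tissue (bottom); symbols mark the sample number and lines the group means of 3. RUNX2 overlaps between the fibroblast groups (10.6 TPM in siRUNX2 3, 7.52 TPM in siControl 1), while all 4 genes separate keloid from normal skin.

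The second comparison asks how keloid tissue differs from normal skin. RUNX2 was at 6.07, 8.16 and 10.8 CPM in normal skin 1 to 3 and at 62.5, 41.9 and 118.5 CPM in keloid 1 to 3. The log2 fold change was 2.91 (SE 0.40, 7.52-fold higher, limma adjusted p = 0.0096). Limma called 321 genes higher and 170 lower in keloid tissue, and with the replicate block 681 and 466, which included all 491. Among the largest rises were ASPN, the asporin gene (20.6 ± 4.61 CPM in normal skin, 1304 ± 720.2 CPM in keloid), the metalloprotease gene ADAM12 (12.3 ± 6.76 and 695 ± 312 CPM), SFRP4, a secreted Wnt modulator gene (5.57 ± 1.14 and 229 ± 112 CPM), and FN1, the fibronectin gene (383 ± 161 and 9223 ± 3903 CPM). COL10A1, a collagen gene of hypertrophic cartilage, rose from 0.602 ± 0.323 to 77.8 ± 84.1 CPM (limma adjusted p = 0.00721). LRRN3 and SLC24A2 rose as well, by 4.63 and 4.48 on the log2 scale.

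Fibrillar collagens rose in keloid tissue as a list, with a median log2 fold change of 3.93 (15.2-fold, camera adjusted p = 1.8e-11, adjusted p = 0.111 with an estimated correlation) and 7 of 9 members called. COL1A1 averaged 1047 ± 602 CPM in normal skin and 22114 ± 20096 CPM in keloid (log2 fold change 4.09, SE 0.84, limma adjusted p = 0.0381). COL1A2, COL3A1 and COL5A2 rose by 4.03, 3.93 and 4.13, and COL11A1 by 5.70. COL5A1 and COL24A1 rose by 3.62 and 1.90. COL5A3 and COL27A1 had log2 fold changes of 1.86 and 0.81 and were not called. Adjusted over the list alone, 8 of 9 were higher. Of the 43 matrix glycoprotein genes 16 were called higher and 0 lower (median 1.97; 30 and 1 with the replicate block), including POSTN, the periostin gene, at 212 ± 41.6 and 4891 ± 2510 CPM. Of 33 collagen processing genes 12 were called higher (median 1.58, 21 with the replicate block), among them ADAMTS2, LOX and SPARC. Of 25 matrix protease genes 11 were called higher (median 1.83, 17 with the replicate block), among them FAP and CTSK. Of 27 other collagens 5 were called higher and 0 lower (median 0.79; 9 and 3 with the replicate block), including COL12A1 and COL6A3. Adjusted over the list alone, 32 glycoprotein, 22 processing, 19 protease and 10 other collagen genes were higher and 1, 1, 1 and 3 lower. The replicate block moved these lower counts to 2 for glycoprotein and 0 for protease genes. Camera called these 4 lists higher, and with an estimated correlation the adjusted p was 0.24 for the other collagens and 0.111 for the rest.

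Mesenchymal-type keloid fibroblast genes showed the lowest list p, with 21 of 28 called higher and a median of 3.16 (camera adjusted p = 2.32e-32, adjusted p = 0.111 with an estimated correlation). This list was chosen as genes of keloid fibroblasts and includes RUNX2. It also shares genes with the collagen, processing, glycoprotein, protease and TGF-beta lists, so its rise is not separate support. In TGF-beta signalling 5 of 26 genes were called higher (median 0.61), among them TGFB3, a TGF-beta ligand gene, at 9.53 ± 2.99 and 159 ± 39.1 CPM, and GREM1. In the osteoblast list 3 of 18 were called higher, among them RUNX1 and COL10A1 (median 0.65, 6 called with the replicate block). Interferon response genes were higher in 30 of 30 cases (median 0.83), with 1 called, IFI6, and 7 with the replicate block. In this list 1 gene was higher adjusted over the list alone, or 12 with the replicate block. The p53 response list (median 0.51), T and NK cells (0.77), B and plasma cells (1.77) and mast cells (0.82) were called higher too. In the mast cell list the protease gene CPA3 passed on its own, and 2 genes passed with the replicate block. With an estimated correlation the adjusted p of the lists in this paragraph lay between 0.111 and 0.432. The p53 call ended without normal skin 1 (adjusted p = 0.0686), normal skin 2 (0.0679), keloid 1 (0.173) or keloid 3 (0.0821). Without keloid 2 the T and NK cell and B and plasma cell calls ended (adjusted p = 0.296 and 0.228), with medians of 0.31 and 1.06.

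Genes of the sweat and sebaceous glands had the lowest list median. All 28 tested were lower in keloid tissue, with a median of -2.54 (5.83-fold, camera adjusted p = 8.42e-20, adjusted p = 0.17 with an estimated correlation), and 13 were called. AWAT2 and DGAT2L6, acyltransferase genes of sebum lipids, averaged 58.0 ± 31.7 and 33.0 ± 10.4 CPM in normal skin and 1.28 ± 2.14 and 0.631 ± 1.00 CPM in keloid. THRSP and SEC14L6 fell by 4.74 and 4.90 on the log2 scale. Other large falls were those of PM20D1, KRT79, AADACL3, ALOX15B and CYP4F8, between -4.66 and -5.59. In edgeR the calls of KRT79 (adjusted p = 0.0793), AWAT2 (0.0824) and ALOX15B (0.0851) ended. Cholesterol synthesis genes had a median of -1.35 with 7 of 23 called lower (13 with the replicate block), among them HMGCS1 at 490.5 ± 152 and 74.1 ± 32.2 CPM. Basal keratinocytes (median -1.12, 2 of 17 called, among them KRT15, and 6 with the replicate block), differentiated keratinocytes (-1.35, 1 of 26 called, KRT77, which is also in the gland list, and 12 with the replicate block), adipocytes (-1.46, 2 of 15 called, CIDEA and PLIN4, and 7 with the replicate block) and melanocytes (-0.80, 0 of 13 called, 1 with the replicate block) were lower as lists. Adjusted over the list alone 16 gland, 12 cholesterol, 10 basal, 13 differentiated, 6 melanocyte and 7 adipocyte genes were lower, the last count being 14 with the replicate block. So were hair follicle (-1.12), skeletal muscle (-0.68), Schwann cell (-0.40), immediate early (-0.79) and proliferation genes (-0.46). Wound-type keratinocyte genes were also called lower (-0.84), but their medians in pairs 1 to 3 were -3.40, -1.77 and 2.55. With an estimated correlation the adjusted p of the lists in this paragraph lay between 0.111 and 0.499. The Schwann cell call ended with the replicate block (adjusted p = 0.0565) and with length and GC correction (0.0978, median -0.43). It also ended without normal skin 1 (0.0949), normal skin 3 (0.199), keloid 1 (0.25) or keloid 2 (0.0544). The medians of these last fits ran from -0.10 (without normal skin 3) to -0.52. The skeletal muscle call ended with length and GC correction (median -0.72, adjusted p = 0.0999). It also ended without normal skin 1 (0.0563), normal skin 3 (0.0582) or keloid 1 (0.142), with medians of -0.40 to -0.55. Without normal skin 1 (adjusted p = 0.299), normal skin 2 (0.151) or keloid 1 (0.39) the wound-type call ended. The hair follicle call ended without normal skin 2 (adjusted p = 0.601) or keloid 1 (0.0703), and without normal skin 2 its median changed sign to 0.42.

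The list calls, 13 higher and 12 lower of 37, are from camera with its preset correlation. With an estimated correlation 0 were called (smallest adjusted p = 0.111), and fry called 13 (smallest adjusted p = 0.0112), or 0 with the replicate block (0.0931). On the recovered reads edgeR called 252 genes higher and 93 lower, or 526 and 326 with the replicate block, and DESeq2 880 and 535. The limma counts rest on single libraries. They were 4 higher and 0 lower without normal skin 1, 191 and 77 without normal skin 2, 83 and 40 without normal skin 3, and 279 and 89 without keloid 2. Without normal skin 1 RUNX2 kept a log2 fold change of 2.73 with an adjusted p of 0.0724 (range over all alternatives 3.81e-09 to 0.0743), and of the other 16 genes with the largest changes ASPN, ADAM12 and SFRP4 passed. Normal skin 1 had the largest share of mitochondrial ribosomal RNA (55.5%).

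**Figure D2:**
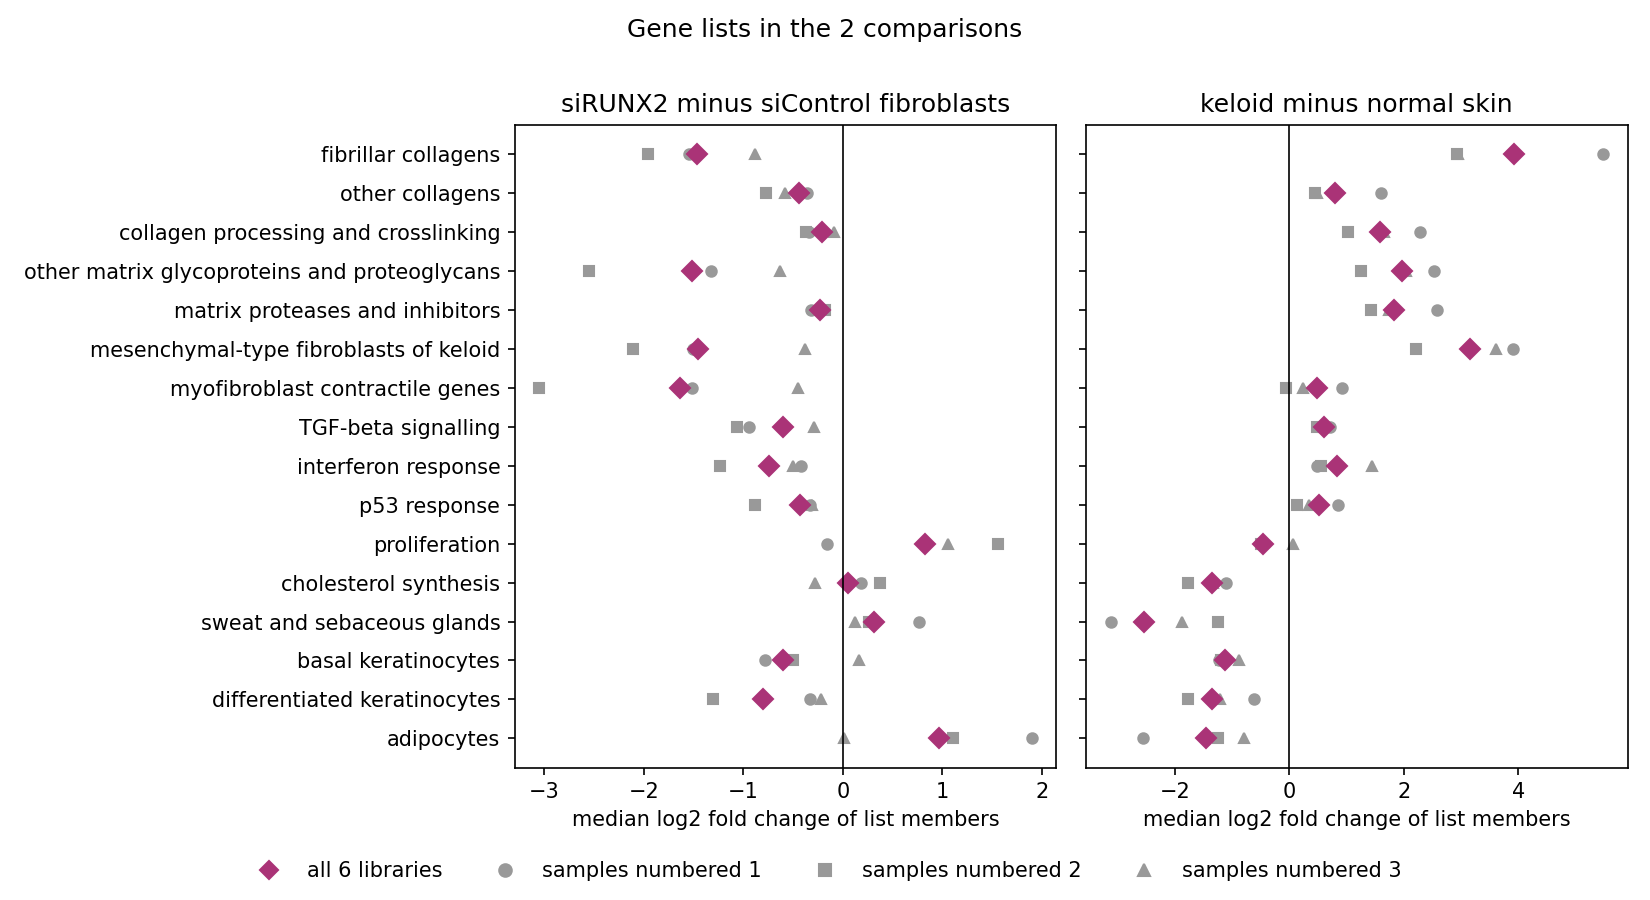
Median log2 fold change of the members of 16 gene lists after RUNX2 knockdown (left) and in keloid against normal skin (right); diamonds use all 6 libraries and grey symbols the same-numbered pairs. Fibrillar collagens lie at -1.46 on the left and 3.93 on the right, and gland genes at -2.54 on the right.

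The third comparison asks whether genes that differ in keloid tissue move after RUNX2 knockdown, over 12710 genes tested in both. Of these, 260 were called higher and 68 lower in keloid tissue (523 and 188 with the replicate block). Of the 260 genes called higher, 192 (73.9%) had lower values after knockdown, with a median log2 fold change of -0.44. At an unadjusted p under 0.05, 77 were lower and 5 higher. The 214 of these genes outside the matrix lists had a median of -0.35. They still include genes of the contractile and mesenchymal-type lists, such as ITGA11 and SULF1. Matrix genes that are in none of the lists were not removed either. Over all 15302 genes tested in fibroblasts the median was 0.045, with 1032 lower and 1260 higher at an unadjusted p under 0.05. Among the 77, the 6 with the largest sum of absolute log2 fold changes were COL11A1, ITGA11, ASPN, SFRP2, ANGPTL2 and SULF1. SFRP2 averaged 34.1 ± 37.2 and 0.289 ± 0.44 TPM in siControl and siRUNX2 cells, and 49.4 ± 14.6 and 550.1 ± 319 CPM in normal skin and keloid. Its log2 differences after knockdown were -4.75, -6.23 and 0.34 in pairs 1 to 3, so it was not lower in sample 3. SULF1, a heparan sulfatase gene, averaged 54.9 ± 45.1 and 1.64 ± 1.18 TPM, and 27.9 ± 5.84 and 267 ± 109 CPM. The 68 genes called lower in keloid tissue had 34 lower and 34 higher values after knockdown. As a list the 260 genes were lower by camera (adjusted p = 2.54e-12), also with an estimated correlation (adjusted p = 0.0187) and by fry (adjusted p = 0.00401). With an estimated correlation and the replicate block they were not (adjusted p = 0.157). No gene was called in the knockdown, so the overlap of calls was 0. Across genes, which are not independent replicates, Spearman's rho of the fold changes was -0.18 and Pearson's r -0.24.

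**Figure D3:**
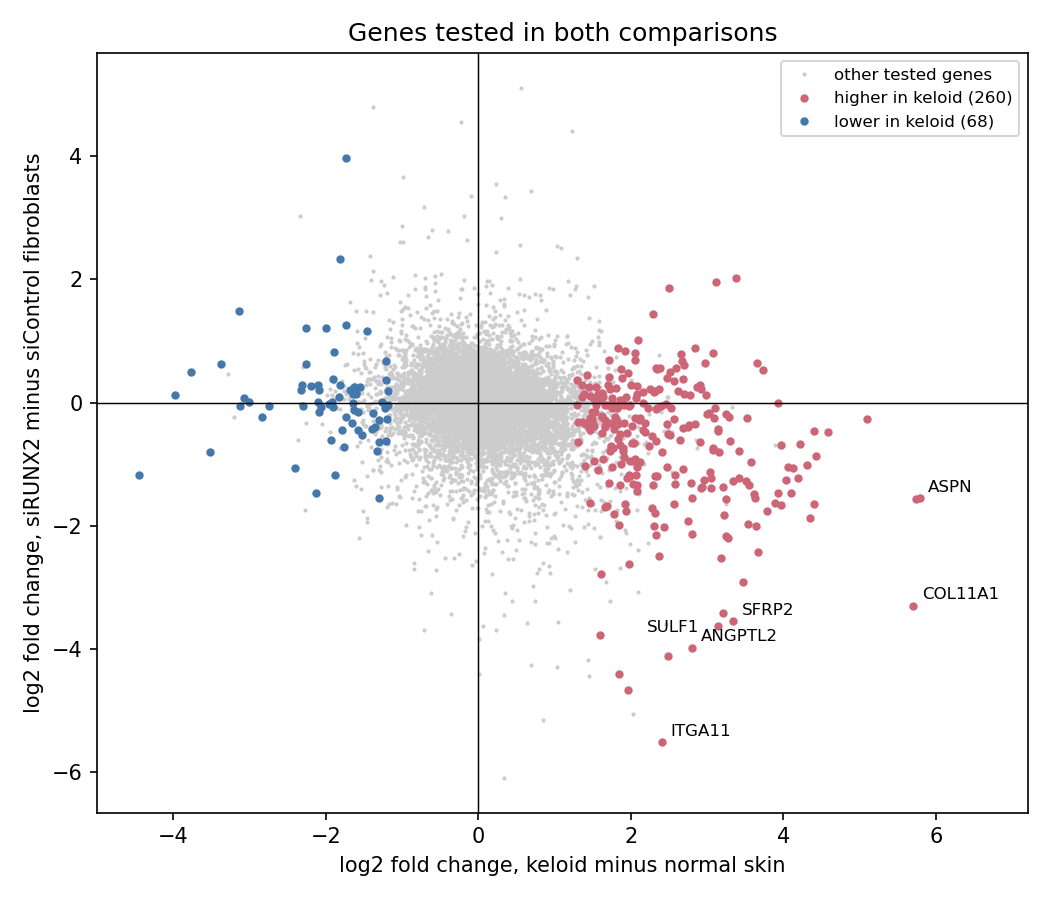
Log2 fold change in keloid against normal skin (horizontal) and after RUNX2 knockdown (vertical) for 12710 genes; red points are the 260 genes called higher and blue points the 68 called lower in keloid tissue. Of the red points, 192 lie below 0 on the vertical axis.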

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

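Chosen after the data were seen were the fits with protein-coding genes alone, without sample 3 in both fibroblast groups, with length and GC correction, without mitochondrial ribosomal RNA, with its share as a covariate, and without normal skin 1 and keloid 3.

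The 0 calls after RUNX2 knockdown stayed at 0 under the pseudocounts, filters, scalings, robust prior, 2-fold minimum, replicate block and length and GC correction. Leaving out single libraries gave 0 to 90 genes higher and 0 to 141 lower, and 0 to 25 genes lower after knockdown and higher in keloid. Without sample 3 in both groups 313 were higher and 362 lower, from 4 libraries. The lists called higher went from 2 to 1 with the replicate block plus length and GC correction, and to 1 to 3 when single libraries were left out. Length and GC correction alone ended the ribosomal protein call (adjusted p = 0.115) and gained that of adipocytes (0.0426), so that 2 lists were still higher, and it ended the papillary and pericyte calls and gained that of mitochondrially encoded genes (0.0433). The adipocyte list was also called with both pseudocounts, median scaling and quantile normalization, and without siControl 3, siRUNX2 2 or sample 3 in both groups. The matrix protease list was called lower with a filter of at least 5 (camera adjusted p = 0.0382) or without siRUNX2 2 (0.0434). The hair follicle list was called lower without siControl 3 or without sample 3 in both groups. Of the lists called lower, the papillary, pericyte and chondrocyte calls also ended with no filter, the papillary and pericyte calls with median scaling, the papillary call with a filter of at least 5, and the pericyte call with quantile normalization or protein-coding genes alone. With an estimated correlation, or by fry, 0 lists were higher and 0 lower. RUNX2 stayed lower and uncalled in every fit run, at -0.29 to -0.94 on the log2 scale when single libraries were left out.

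In keloid tissue, against 321 higher and 170 lower, the paired fit with the replicate block called 681 and 466, and with length and GC correction too 1076 and 878. That correction alone gave 749 and 565, no filter 186 and 75, and quantile normalization 292 lower. The count test edgeR called 93 lower, 90 lower without mitochondrial ribosomal RNA, and 526 and 326 with the replicate block, whereas DESeq2 called 880 and 535. The mitochondrial share as a covariate gave 536 and 511. Leaving out single libraries gave 4 to 279 higher and 0 to 154 lower, and leaving out normal skin 1 and keloid 3 gave 3 and 0. Of the lists, 0 were higher and 0 lower with an estimated correlation, and 8 and 5 by fry. The p53, B and plasma, Schwann, skeletal muscle and wound-type calls ended with a filter of at least 5, and the Schwann and skeletal muscle calls also with quantile normalization and with length and GC correction. Lists not called that at least 1 alternative called were those of endothelium, chondrocytes, ribosomal proteins, hypoxia, macrophages and mitochondrially encoded genes. RUNX2 stayed higher, at 2.51 to 3.25 on the log2 scale when single libraries were left out, and lost its call without normal skin 1 (2.73) and without normal skin 1 and keloid 3 (2.33). The cause of these changes was not tested, except that fits without a library have fewer samples. Depth limits the tissue values below 0.146 to 0.304 CPM, the worth of 3 reads, and is unknown for the TPM values.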

Other observations

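The 4 genes of smallest p in the inflammatory list had values in both directions after RUNX2 knockdown, and none passed limma's threshold. CXCL5 averaged 3.87 ± 5.96 TPM with siControl and 78.1 ± 58.2 TPM with siRUNX2, CXCL1 1.29 ± 1.78 and 6.67 ± 1.87 TPM, and IL8 1.18 ± 1.42 and 6.68 ± 2.47 TPM, whereas CXCL12 averaged 35.6 ± 23.4 and 4.26 ± 7.26 TPM. Adjusted over the inflammatory list alone 5 genes were higher and 3 lower, but 0 and 0 with the replicate block, and camera did not call the list (adjusted p = 0.495, median -0.63). PPARG, the main transcription factor of fat cells, averaged 9.36 and 46.1 TPM and the lipase inhibitor gene G0S2 13.1 ± 7.96 and 118 ± 94.2 TPM, in an adipocyte list that was not called (median 0.96, adjusted p = 0.0511; 0.0426 and called with length and GC correction). In the osteoblast list, not called (median -0.15), SMOC1 averaged 2.30 ± 1.61 and 32.6 ± 19.6 TPM and TNFRSF11B, the osteoprotegerin gene, 261 ± 230.4 and 3.79 ± 2.26 TPM. ANGPTL4 averaged 2.88 ± 1.84 and 186 ± 181 TPM, in a hypoxia and glycolysis list with a median of 0.23. The unfolded protein list had a median of 0.09 and a mean of -0.13, with the chaperone gene HSPA5 at 839 ± 92.3 and 1363 ± 155 TPM. Cholesterol synthesis (0.06, mean -0.01), immediate early (0.10) and mitochondrially encoded genes (-0.10) had medians near 0. The skin cell lists were not called in the main fit. Their medians were -0.60 for basal and -0.80 for differentiated keratinocytes, -1.09 for hair follicle and 0.31 for glands. Melanocytes were at -0.01, endothelium at 0.48 and T and NK cells at 0.36. The hair follicle list, with 3 tested members, was called lower without siControl 3 (median -1.79, camera adjusted p = 0.00565). Without sample 3 in both groups it was called lower too (-1.70, 0.0145). Wound-type keratinocyte, Schwann, B and plasma, macrophage, mast, skeletal muscle and red blood cell lists had fewer than 3 tested members.

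In keloid tissue some lists that were not called held genes that were. SFRP2 and WISP2 were higher in the reticular fibroblast list, whose median was -0.38 and mean 0.18. Chondrocyte genes had a median of 0.60, with ACAN, the aggrecan gene, called at 1.18 ± 0.273 and 27.6 ± 25.7 CPM, and SOX9 at 44.1 ± 7.96 and 11.5 ± 10.3 CPM, not called. The contractile list had a median of 0.49, with 3 members called higher (CDH11, ITGA11 and PALLD) and 2 lower, among them DES. In the macrophage list (median 0.29) MSR1 was called higher, in the inflammatory list (-0.36) TNFAIP6 was higher, and in the hypoxia list (-0.16) EGLN3 was lower and P4HA1 higher. Unfolded protein (0.26), ribosomal protein (-0.20), mitochondrially encoded (-0.73), papillary fibroblast (0.27), endothelial (0.38) and pericyte genes (-0.18) were not called. The mitochondrially encoded list was called lower with the replicate block (adjusted p = 0.00358, against 0.0566 without it), and the red blood cell list had 2 tested members.

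Chosen after the result they bear on was seen were the tests of single cultures, of both forms of dilution and of the share of epidermis below.

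Fibrillar collagen, matrix glycoprotein and contractile genes were lower after knockdown, with a pooled median of -1.51 over 60 genes, although RUNX2 itself differed by -0.63 and did not pass. Transcript length or GC content bias is argued against: correction left the pooled median at -1.41 (SD of the members 1.35). Lists matched on length, GC and expression had medians of only -0.11 to 0.11 (5th to 95th percentile). That 0 of 10000 such lists were as low adds no support, since these genes were picked as lower. A difference between single cultures stays open: 3 of 3 same-numbered pairs had a pooled median under -0.5 (-1.45, -2.36 and -0.67), but these genes were picked as lower in the same libraries, and each pair is itself a difference between single cultures. In 2 of the 10 splits of the 6 libraries at least as many genes had an unadjusted p under 0.05, 2423 against 2292 in the real one, and 10 splits are too few for a share under 0.05; the larger one sets siControl 1 and siRUNX2 1 and 2 against the rest, and the other splits that part all pairs gave 84 to 846. An effect of the siRNA on matrix genes stays a hypothesis, and whether it acts through RUNX2 was not tested, since the labels name a single siRNA target and its level overlapped between groups.

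Gland, adipocyte and keratinocyte genes were lower in keloid tissue, and length and GC correction left the gland median at -2.55. A first test of a common dilution of epidermal and fat genes by the transcripts that rose allowed it. The median of the gland list minus that of the differentiated keratinocyte list, which share KRT77, averaged -0.88 over the pairs (-2.51, 0.53 and -0.67), less than its SD of 1.53. A second test was added after that result, and argues against a large dilution of all transcripts: in plain CPM, without the deposited scaling, all 16349 tested genes had a median log2 fold change of 0.0149 and the endothelial list 0.39, against -2.57 for glands. Plain CPM includes mitochondrial ribosomal RNA, whose share ran from 22.9% in keloid 1 to 55.5% in normal skin 1, so a small dilution is not excluded. A smaller share of epidermis and appendages in the keloid samples cannot be told apart from lower expression per cell without values per cell: 16 of 18 medians of 6 such lists in 3 pairs were below 0, but these lists had been called lower in the same libraries, and their falls were unequal, from -0.49 (hair follicle) to -3.40 (wound-type) in pair 1, with 0 and 2.55 in pair 3. The real split called 491 genes and the highest other split 1, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.

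One other split of the tissue libraries moved more genes than the real one at an unadjusted p under 0.05, 3232 against 2672 in fits without the replicate block, although it called 1, and the other splits that part all pairs gave 106 to 608. It sets normal skin 1, normal skin 3 and keloid 3, the libraries with the largest mitochondrial ribosomal RNA share, against the rest. Since this keeps pairs 2 and 3 whole on opposite sides, it contrasts these pairs as much as the share. The libraries of pair 3 also had fewer genes above 0 (22638 and 23083, against 28612 to 30732 in the other tissue libraries). Their share of other mitochondrial RNA was larger, at 8.53% and 6.84% against 1.95% to 4.49%. Mitochondrial ribosomal RNA taking reads from other genes stays open, since scaling without it left 3245 genes but shifted the libraries against each other by at most 0.09 on the log2 scale, too little to be a test. GC content or length bias between libraries stays open: correction left 1672 genes, 51.7% of the number before, just above the bound of at most 50% set beforehand, and fold changes in that split had a Spearman's rho of -0.66 with GC content across 13780 genes. No biological explanation was tested, and with the share as a covariate limma called 536 genes higher and 511 lower in keloid tissue.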
